A study of Mus musculus with 9 samples.

How the data were processed

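The sources were the authors' deposited tables for 9 libraries and the sample labels. Per the submitters' processing notes, reads were aligned to mm10 with STAR, quantified with HOMER and compared with DESeq2; versions are not given in the sources used here. Per the file headers, the count table holds raw read counts over exons per gene, condensed to 1 transcript per gene. The authors' deposited TPM table lists 23203 genes and lacks 1334 of the 24537 genes of the count table, of which 1329 are non-coding, and its TPM values equal the deposited counts divided by transcript length to within 0.0014. The authors' deposited comparison table holds log2 fold changes and p-values for 18313 genes, and its second population comparison carries the same NCD heading as the first. Positions are those of the transcripts named in the deposited count table, on mm10. All columns of the tables were assigned a use, with 0 left over. Smart-seq2 does not mark the strand, so counts of overlapping genes on opposite strands are uncertain. Those of close paralogs such as MHC, chemokine, insulin and globin genes are uncertain too.

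Raw counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (14226 genes), scaled with TMM, and fitted with 4 group means over all 9 libraries and the quasi-likelihood F-test. Genes with Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were CD11cHi against F480Hi on NCD, on HFD and averaged over diets, HFD against NCD in CD11cHi, in F480Hi and averaged over populations, and the interaction. CPM values are TMM-scaled and log CPM used a prior count of 2. These choices, the alternatives and 49 gene lists were fixed before the data were examined, except for 3 alternatives chosen after seeing the data: removal of rRNA-derived genes, scaling to macrophage core genes, and a stromal score as covariate. A score that differs between the groups compared takes up part of their difference whatever its source.

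Of the 49 lists 47 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data. The estimate rests on 5 residual degrees of freedom. With it, 4 lists kept their call on NCD and 2 in the averaged population difference, and 0 in the other 5 comparisons.

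Genes were named by a rule fixed before the data were examined. In each comparison the rule took genes with adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap of CPM between the groups compared (not required for the interaction), and kept the 10 largest positive and 10 largest negative log2 fold changes outside predicted, non-coding and cell type marker genes. It added the sort markers in every sample and the 4 called members with the largest absolute log2 fold change of each list. The rule gives 911 called pairs of gene and comparison. The text does not show them all, and its choice was made after seeing the data: genes whose call held with any 1 library left out were preferred. Of the 911 pairs 483 held in every such run, 428 were lost in at least 1 and 200 were reversed in some setting. The text names 152 of them, of which 149 held, 3 were lost and 17 were reversed. The 759 not named had 334, 425 and 183, so the named genes are steadier than the rule's genes as a whole. In the 4 direct comparisons 118 of 118 named called pairs had no overlap of CPM between groups, which the rule itself required for part of them. By chance alone that happens in 33.3% of genes for 2 libraries against 2 and in 20% for 3 against 2. The named pairs were all chosen as called, which itself favours no overlap, so their count is not evidence.

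For genes with 3 or fewer counts in the lower group no fitted fold change is given. With 0 counts the fold is a floor set by 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact 95% interval. Floors and intervals cover counting error only and leave out variation between libraries.

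The code was tried on simulated counts built from these libraries, with 50 genes changed at each of 4 folds. On NCD it recovered 14% of 2-fold changes, 60% of 4-fold, 88% of 8-fold and 84% of 16-fold, and on HFD 12%, 72%, 82% and 90%. For diet in CD11cHi it recovered 14%, 64%, 80% and 94%, and in F480Hi 8%, 58%, 74% and 76%. False calls were 11.5%, 4.5%, 8.7% and 10% of calls in these 4 comparisons, so 3 of them exceed the nominal 5%. Small changes are mostly missed with this number of libraries. Each simulation changed 200 genes, up and down alike, from a mean common to all groups. It held no shift in RNA make-up such as these libraries show, so its rates need not hold for the real comparisons.

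Log2 CPM of replicates correlated from 0.899 in F480Hi on HFD to 0.964, and no 2 replicates of a group were duplicates (chi-square per degree of freedom 21.7 to 80.8). Libraries had 14745 to 16661 genes with a count, and 3 counts corresponded to 0.241 to 0.622 CPM.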

Results

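Islets of the pancreas hold macrophages, and these libraries compare macrophages sorted from islets of C57BL/6J mice on normal chow (NCD) or a high fat diet (HFD). Cells were sorted with antibodies to CD11b, CD11c and F4/80, and RNA of the sorted cells was copied and amplified with Smart-seq2, a full-length cDNA protocol for small cell numbers. The 9 libraries fall into 4 groups by the population sorted, F480Hi or CD11cHi, and by diet. There are 2 libraries of F480Hi on NCD, 2 of F480Hi on HFD, 2 of CD11cHi on NCD and 3 of CD11cHi on HFD. Groups are named throughout by their labels. Nothing in the labels says that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical.

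Total gene counts, in M (mega), were 5.45, 10.9 and 11.2 in CD11cHi on HFD (replicates 1 to 3) and 10.8 and 8.74 in CD11cHi on NCD. They were 12.5 and 10.8 M in F480Hi on HFD and 11.1 and 10.1 M in F480Hi on NCD. Of these, 31.3% to 48.6% fell on Rn45s, the ribosomal RNA precursor, and the counts outside 3 genes that overlap ribosomal RNA (Rn45s, Lars2 and Mir6236) ranged from 2.51 to 6.64 M. Hormone and other endocrine cell transcripts made up a large part of that remainder. The 2 endocrine marker lists held 26.4% ± 3.66 (SD, n = 2) of it in F480Hi on HFD and 22.9% ± 4.63 (SD, n = 3) in CD11cHi on HFD. They held 7.78% ± 3.67 (SD, n = 2) in CD11cHi on NCD and 0.812% ± 0.025 (SD, n = 2) in F480Hi on NCD. The first 2 principal components of log2 CPM held 39.8% and 28% of the variance. Below, ± after a log2 fold change is its standard error, and ± after a CPM value is the SD over the libraries of the group. Adjusted p is from edgeR's quasi-likelihood test unless another test is named.

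The genes of the sort antibodies were read first. Itgax, which encodes CD11c (NM_021334, chromosome 7, 128129568 to 128150657 in mm10), had 62 and 131 counts in F480Hi on NCD and 1044 and 313 in F480Hi on HFD. In CD11cHi it had 1432 and 1718 on NCD and 1365, 2476 and 2099 on HFD. It was higher in CD11cHi on NCD (log2 fold change 4.36 ± 0.49, adjusted p = 0.000248) and on HFD (2.08 ± 0.41, adjusted p = 0.00706; -0.05 with a stromal score as covariate). Adgre1, which encodes F4/80 (NM_010130, chromosome 17, 57358686 to 57483529), had 6021 and 6981 counts in F480Hi on NCD and 1651 and 1532 in F480Hi on HFD. It had 2536 and 3179 in CD11cHi on NCD and 1558, 2863 and 2733 in CD11cHi on HFD. On NCD it was not called between the populations (-0.85 ± 0.25, adjusted p = 0.055). On HFD it went against the labels and was higher in the libraries labelled CD11cHi (1.06 ± 0.24, adjusted p = 0.0134). This call was lost without CD11cHi HFD replicate 3 (0.99, adjusted p = 0.0529) or F480Hi HFD replicate 2 (1.11, adjusted p = 0.0552), and also with a stromal score as covariate or macrophage core scaling. Itgam, which encodes CD11b (NM_008401, chromosome 7, 128062640 to 128118491), had 2546 and 2209 counts in F480Hi on NCD and 390 and 1397 in F480Hi on HFD. It had 1263 and 1024 in CD11cHi on NCD and 169, 275 and 484 in CD11cHi on HFD. It was not called between the populations on NCD (-0.73 ± 0.51, adjusted p = 0.483) or HFD (-1.11 ± 0.46, adjusted p = 0.166).

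**Figure D1:**
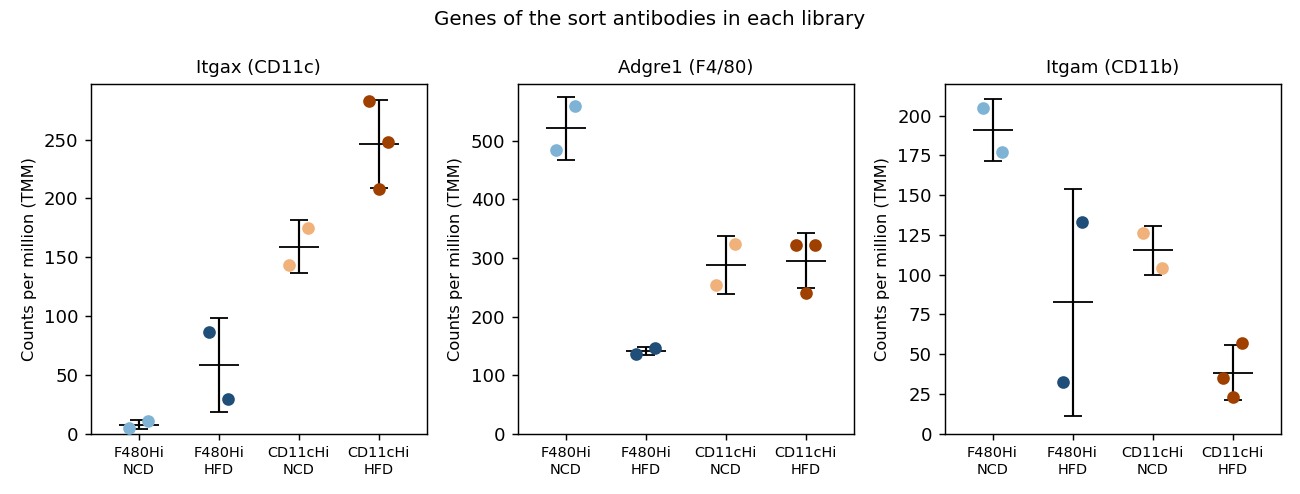
CPM (TMM-scaled, linear axis) of Itgax, Adgre1 and Itgam in each library (points), with the group mean and SD (lines). Adgre1 averaged 522 CPM in F480Hi on NCD and 141 CPM in F480Hi on HFD, where it lay below its mean of 295 CPM in CD11cHi on HFD.

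With TMM scaling the median log2 fold change over all genes was -0.01 and -0.04 for the population difference on NCD and HFD and -0.03 and 0.00 for the diet difference in CD11cHi and F480Hi. Other scalings moved it. On the log2(TPM + 1) scale it was -0.31 and 0.10 for the population difference on NCD and HFD, -0.35 and -0.76 for the diet difference in CD11cHi and F480Hi, -0.58 for the averaged diet difference and 0.37 for the interaction. With a pseudocount of 0.1 these were -0.34, 0.12, -0.41, -0.86, -0.67 and 0.41. Scaling to macrophage core genes, chosen after seeing the data, gave 0.37, -0.71, 0.16, 1.24, 0.67 and -1.11, and -0.14 for the averaged population difference. Directions below are those with TMM, and a list whose direction another scaling turns is named as such. Relative to the median of all genes, none of the lists called in a comparison changed sides under the 6 other scalings. Where a scaling changes only library sizes, it shifts all genes nearly alike. Taking off the median then cancels the shift, so this check could hardly fail there.

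Some genes named below follow RNA of other islet cells. Of 100 named genes outside the beta, other endocrine, acinar, ductal, endothelial and stromal lists, 20 had a Pearson r of at least 0.9 between log2 CPM and the sum of 1 of these lists over the 9 libraries, a threshold chosen after seeing the data. With beta cell markers these were Vegfa, Muc4, P2ry1, Defb1, Ncam1 and Asns, and with other endocrine markers Kcnk3, Pdk4, Serpina7, Tmem59l, Gc and Pdyn. With endothelial markers they were Myh11, Olfr558, Timp3 and Heyl, with stromal markers C1s1, Fbn1 and Ddr2, and with acinar markers Serpini2. Differences of these 20 genes cannot be assigned to macrophages. Genes just under the threshold carry a like doubt, among them Cxcl13 (r = 0.893, stromal), Ccl5 (0.888, beta cell), Oas3 (0.849, beta cell) and Tnxb (0.84, stromal). The sort marker gene Itgax is another (0.838, beta cell). Ifi44 (0.801, other endocrine), Ednrb (0.8, stromal), Creld2 (0.794, other endocrine), Mreg (0.791, beta cell) and Mmp12 (0.79, beta cell) followed. A lower r does not assign a gene to macrophages. Markers of natural killer, T, dendritic and erythroid cells were not part of this check.

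The first comparison asks how the CD11cHi and F480Hi libraries differ on normal chow. Part of the MHC class II genes, which present antigen, and most dendritic cell genes were higher in CD11cHi, and part of the scavenger and tissue macrophage genes were higher in F480Hi. With an estimated correlation the dendritic cell lists kept their call (adjusted p = 0.0433 each), and MHC class II and scavenger genes did not (adjusted p = 0.194 and 0.297). The MHC class II list summed to 22400 ± 354 CPM in CD11cHi and 13900 ± 141 in F480Hi (SD, n = 2 each). Of its 11 measured members 5 were higher, 0 lower and 6 not called (8 higher adjusted over the list alone; camera adjusted p = 4.67e-07, and adjusted p = 0.194 with an estimated correlation). Among them were H2-Oa and H2-Ob, which form the nonclassical heterodimer that restrains peptide loading, with log2 fold changes of 3.72 ± 0.50 (adjusted p = 0.000796) and 1.87 ± 0.32 (adjusted p = 0.00406). Of the 29 scavenger and tissue macrophage genes, 12 were lower in CD11cHi, 0 higher and 17 not called (21 lower adjusted over the list alone; camera adjusted p = 1.43e-11, and adjusted p = 0.297 with an estimated correlation). Their sum was 4950 ± 396 CPM against 14200 ± 2120. Cell cycle genes summed to 610 ± 73.5 CPM in CD11cHi and 386 ± 53 in F480Hi, with 1 of 33 higher and 32 not called (0 adjusted over the list alone; camera adjusted p = 0.00344, and adjusted p = 0.64 with an estimated correlation).

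Most dendritic cell genes were higher in CD11cHi on NCD. Of 10 markers of type 1 conventional dendritic cells (cDC1) 9 were higher in CD11cHi and 1 was not called (9 adjusted over the list alone), and the sum was 910 ± 48.8 CPM against 316 ± 30.4. Of 12 markers of type 2 and all conventional dendritic cells 9 were higher and 3 not called (10 adjusted over the list alone), with sums of 530 ± 77.8 and 138 ± 14.8 CPM. Both lists held with an estimated correlation (camera adjusted p = 0.0433 each). Xcr1, a chemokine receptor of cDC1 (NM_011798, chromosome 9, 123852315 to 123862029), had a log2 fold change of 5.93 ± 0.91 (adjusted p = 0.00193). Flt3, the receptor of the dendritic cell growth factor Flt3 ligand (NM_010229, chromosome 5, 147330742 to 147400489), had one of 6.74 ± 0.51 (adjusted p = 4.76e-05). Itgae had 455 counts in CD11cHi and 3 in F480Hi, a ratio of 191 (95% counting interval 64.8 to 928). Ccr7, which guides dendritic cells to lymph nodes, was higher by 5.32 ± 0.72 (adjusted p = 0.000796). Markers of plasmacytoid dendritic cells were not called as a list on NCD (464 ± 27.6 CPM in CD11cHi against 425 ± 77.8, camera adjusted p = 0.487). On HFD they were not called either, with a lower sum in CD11cHi (278 ± 23.8 against 350 ± 22.6 CPM, camera adjusted p = 0.377).

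Cytokine and chemokine genes differed on NCD as single genes. Il1b was higher in CD11cHi (2.53 ± 0.35, adjusted p = 0.00096), and Il12b, a subunit of interleukin 12, had 437 counts against 2, a ratio of 275 (75.6 to 2270). Of 14 inflammatory cytokine genes 4 were higher, 0 lower and 10 not called (4 higher adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0554). The chemokine genes Ccl5 (5.02 ± 0.58, adjusted p = 0.000311, r = 0.888 with beta cell markers) and Ccl22 (5.41 ± 0.74, adjusted p = 0.00117) were higher. Their list of 21 had 3 higher, 2 lower and 16 not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.958). Mreg was also higher in CD11cHi (298 counts against 2, ratio 187, 51.4 to 1550). Il2rb and Gcsam had 238 and 217 counts in CD11cHi and 0 in F480Hi, which makes them at least 99.7-fold and 90.9-fold higher (floor of 3 counts over the group). The genes of this paragraph were not compared with markers of natural killer cells, which were higher in the same libraries.

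Markers of other cells moved with the same comparison. All 15 beta cell markers were higher in CD11cHi on NCD (15 adjusted over the list alone). Their sum was 36100 ± 19200 against 1230 ± 127 CPM. Slc2a2, the glucose transporter gene, differed by 5.90 ± 0.57 (adjusted p = 0.00011), and G6pc2 by 5.08 ± 0.47 (adjusted p = 9.68e-05). The mucin gene Muc4, which followed beta cell markers over the libraries (r = 0.986), differed by 5.79 ± 0.44 (adjusted p = 4.76e-05). Of 10 natural killer (NK) cell markers 7 were higher and 3 not called (10 adjusted over the list alone). Their sum was 79 ± 29.7 against 2.45 ± 0.057 CPM, and Nkg7 had 238 counts against 0 (at least 99.7-fold). The beta and NK cell lists held with an estimated correlation (camera adjusted p = 0.0433 each). Stromal markers went the other way, with 11 of 13 lower in CD11cHi, 0 higher and 2 not called (12 lower adjusted over the list alone; camera adjusted p = 1.14e-11, and adjusted p = 0.194 with an estimated correlation). Their sum was 56 ± 20 against 938 ± 272 CPM. Lower in CD11cHi outside that list, and following it over the libraries in the first 2 cases (r = 0.965 and 0.924), were Fbn1, which encodes fibrillin (-5.62 ± 0.77, adjusted p = 0.000871), Ddr2 (-5.53 ± 0.68, adjusted p = 0.00045) and Tnxb (-4.91 ± 0.84, adjusted p = 0.00389). Tnxb followed it less closely (r = 0.84). Adamts5 had 382 counts in F480Hi and 3 in CD11cHi, a ratio of 101 (34.4 to 493). Erythroid markers (sum 1.27 ± 1.51 against 75 ± 20.8 CPM) and endothelial markers (42 ± 9.4 against 128 ± 31.8) were lower in CD11cHi too. T cell markers (24.3 ± 5.52 against 5.5 ± 0.163) and ductal markers (78.2 ± 14.6 against 29 ± 12.9) were higher. Camera called these lists at the preset correlation but not with an estimated one (adjusted p = 0.325, 0.222, 0.173 and 0.147). The matrix remodelling list was not called (2 of 22 higher, 3 lower, 17 not called; 2 and 4 adjusted over the list alone; camera adjusted p = 0.332).

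In all, 1214 of 14226 genes were called on NCD, 811 higher and 403 lower in CD11cHi, and 2987 had an unadjusted p under 0.05. The split was 569 and 858 on log2(TPM + 1), 557 and 623 on log2(TPM + 0.1) and 1020 and 167 with macrophage core scaling. Leaving out any 1 of the 4 libraries compared lowered the count by more than 1.5-fold, to 389 without CD11cHi NCD replicate 1, 625 without replicate 2, 518 without F480Hi NCD replicate 1 and 546 without replicate 2. The count was 1935 with only the groups compared and 105 with a stromal score as covariate, and with a beta cell score edgeR called 0 genes (498 at unadjusted p under 0.05; Fbn1 0.09, Tnxb 0.09, G6pc2 -0.93).

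The second comparison sets the same populations against each other on the high fat diet. All MHC class II genes and part of the cell cycle and macrophage core genes were higher in CD11cHi, while all endothelial and stromal markers and most acinar markers were higher in F480Hi. As lists these were called at the preset correlation, and with an estimated correlation they were not (adjusted p = 0.0985, 0.279, 0.279, 0.0678, 0.16 and 0.279). All 11 MHC class II genes were higher in CD11cHi (11 adjusted over the list alone; camera adjusted p = 6.05e-12, and adjusted p = 0.0985 with an estimated correlation). Their sum was 27800 ± 3940 CPM (SD, n = 3) against 11200 ± 424 (SD, n = 2). H2-Oa differed by 2.22 ± 0.44 (adjusted p = 0.00744) and Ciita, the transactivator of class II genes (NM_001302619, chromosome 16, 10480072 to 10527640), by 1.83 ± 0.29 (adjusted p = 0.00215). Of 10 cDC1 markers 6 were higher and 4 not called (8 adjusted over the list alone; camera adjusted p = 3.31e-09, and adjusted p = 0.0678 with an estimated correlation). Their sum was 506 ± 96.8 against 187 ± 41 CPM. They included the transcription factor gene Irf8 (1.50 ± 0.25, adjusted p = 0.00264) and Wdfy4 (1.81 ± 0.24, adjusted p = 0.000571).

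Macrophage core genes were higher in CD11cHi on HFD in 6 of 18, with 0 lower and 12 not called (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.61e-05, and adjusted p = 0.279 with an estimated correlation). Their sum was 8060 ± 1010 against 5220 ± 1660 CPM. Cebpa, a transcription factor gene of myeloid cells, differed by 1.35 ± 0.23 (adjusted p = 0.00368). The fractalkine receptor gene Cx3cr1 differed by 1.66 ± 0.31 (adjusted p = 0.00515; -0.17 with a stromal score as covariate). Chemokine receptor genes were higher in 7 of 13, with 0 lower and 6 not called (7 adjusted over the list alone; camera adjusted p = 0.00028, and adjusted p = 0.0985 with an estimated correlation). An example was Cxcr4 (1.76 ± 0.32, adjusted p = 0.00493). Cell cycle genes were higher in 7 of 33, with 26 not called (14 adjusted over the list alone; camera adjusted p = 4.05e-09, and adjusted p = 0.279 with an estimated correlation). Their sum was 300 ± 57.6 against 156 ± 14.8 CPM. The mitotic kinesin gene Kif11 differed by 3.06 ± 0.49 (adjusted p = 0.00217). The lysosome list was higher in 7 of 32 (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.96e-06, and adjusted p = 0.279 with an estimated correlation). It turned with macrophage core scaling to 0 higher and 3 lower. The receptor tyrosine kinase gene Axl (1.52 ± 0.27, adjusted p = 0.00431), the lysosomal acid lipase gene Lipa (1.29 ± 0.21, adjusted p = 0.00281) and Parvg (2.36 ± 0.31, adjusted p = 0.000649) were also higher. So were Rnase6 (2.30 ± 0.37, adjusted p = 0.00243) and Ccl5 (2.30 ± 0.46, adjusted p = 0.00722).

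Markers of blood vessels and exocrine cells came next. Endothelial markers were lower in CD11cHi in 11 of 11 (11 adjusted over the list alone; camera adjusted p = 8.99e-33, and adjusted p = 0.0678 with an estimated correlation). Their sum was 41.2 ± 8.11 against 660 ± 210 CPM. Plvap differed by -5.95 ± 0.48 (adjusted p = 2.12e-05) and Emcn by -5.73 ± 0.48 (adjusted p = 2.49e-05). Stromal markers were lower in 13 of 13 (13 adjusted over the list alone; camera adjusted p = 9.34e-20, and adjusted p = 0.16 with an estimated correlation). Their sum was 22.4 ± 15.3 against 1900 ± 1820 CPM. The pericyte gene Rgs5 differed by -8.33 ± 0.78 (adjusted p = 5.79e-05). The smooth muscle gene Myh11 had 799 counts in F480Hi and 2 in CD11cHi, a ratio of 446 (123 to 3690). Heyl and Olfr558 had 461 and 713 counts against 0, at least 171-fold and 265-fold higher in F480Hi. Acinar markers were lower in CD11cHi in 17 of 19, with 2 not called (19 adjusted over the list alone; camera adjusted p = 9.92e-19, and adjusted p = 0.279 with an estimated correlation). Their sum was 2330 ± 2500 against 29500 ± 2120 CPM. Among them, the digestive enzyme genes Pla2g1b and Cela2a differed by -4.92 ± 0.59 (adjusted p = 0.000327) and -4.54 ± 0.78 (adjusted p = 0.00346), and Zg16 by -4.62 ± 0.77 (adjusted p = 0.00281). The somatostatin gene Sst (-6.31 ± 0.65, adjusted p = 0.00011), the complement gene C1s1 (-6.91 ± 0.76, adjusted p = 0.00018, r = 0.985 with stromal markers) and the B cell chemokine gene Cxcl13 (-4.39 ± 0.85, adjusted p = 0.00652) were also lower in CD11cHi. Cxcl13 moved with stromal markers as well (r = 0.893).

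On HFD 1429 genes were called, 625 higher and 804 lower in CD11cHi, and 3409 had an unadjusted p under 0.05. The split was 599 and 568 on log2(TPM + 1), 595 and 524 on log2(TPM + 0.1) and 60 and 3667 with macrophage core scaling, and 945 genes were called with only the groups compared, 866 with the replicate number as block, 941 with a beta cell score as covariate and 17 with a stromal score. The count was 815 without CD11cHi HFD replicate 3 and 624 without F480Hi HFD replicate 2.

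Averaged over diets, 1797 genes differed between the populations, 929 higher and 868 lower in CD11cHi (3579 at unadjusted p under 0.05). The scavenger and tissue macrophage list was lower in CD11cHi in 19 of 29 members, with 0 higher and 10 not called (23 adjusted over the list alone; camera adjusted p = 1.59e-12, and adjusted p = 0.297 with an estimated correlation). It included the hyaluronan receptor gene Lyve1 (-2.52 ± 0.43, adjusted p = 0.00209), the chemokine gene Pf4 (-2.55 ± 0.51, adjusted p = 0.00514) and Cbr2 (-2.18 ± 0.42, adjusted p = 0.0046). Their sums and those of stromal markers were both higher in F480Hi, and with a stromal score as covariate the values were 0.66, 2.35 and 1.29. MHC class II genes were higher in 11 of 11 (11 adjusted over the list alone; camera adjusted p = 3.94e-14, and adjusted p = 0.0674 with an estimated correlation). They included H2-Eb2 (3.72 ± 0.63, adjusted p = 0.00195) and H2-DMb2 (2.91 ± 0.50, adjusted p = 0.00224). The cDC1 list was higher in 10 of 10 (10 adjusted over the list alone) and the second dendritic list in 10 of 12 with 2 not called (11 adjusted over the list alone). Both held with an estimated correlation (camera adjusted p = 0.038 and 0.0377). Xcr1 differed by 5.27 ± 0.65 (adjusted p = 0.000221; -0.04 with a stromal score as covariate) and Ccr7 by 4.47 ± 0.50 (adjusted p = 0.000124). The peptide transporter gene Tap1 differed by 0.88 ± 0.15 (adjusted p = 0.00185) and the cyclin gene Ccnb2 by 1.61 ± 0.35 (adjusted p = 0.00929). The split was 589 and 911 on log2(TPM + 1), 577 and 786 on log2(TPM + 0.1), 501 and 967 with macrophage core scaling, 1093 and 1118 with no expression filter and 615 and 660 without F480Hi NCD replicate 2, and the count was 1143 without CD11cHi NCD replicate 1 and 1187 without replicate 2. With a beta cell score as covariate edgeR called 0 genes (569 at unadjusted p under 0.05), and with a stromal score 5.

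**Figure D2:**
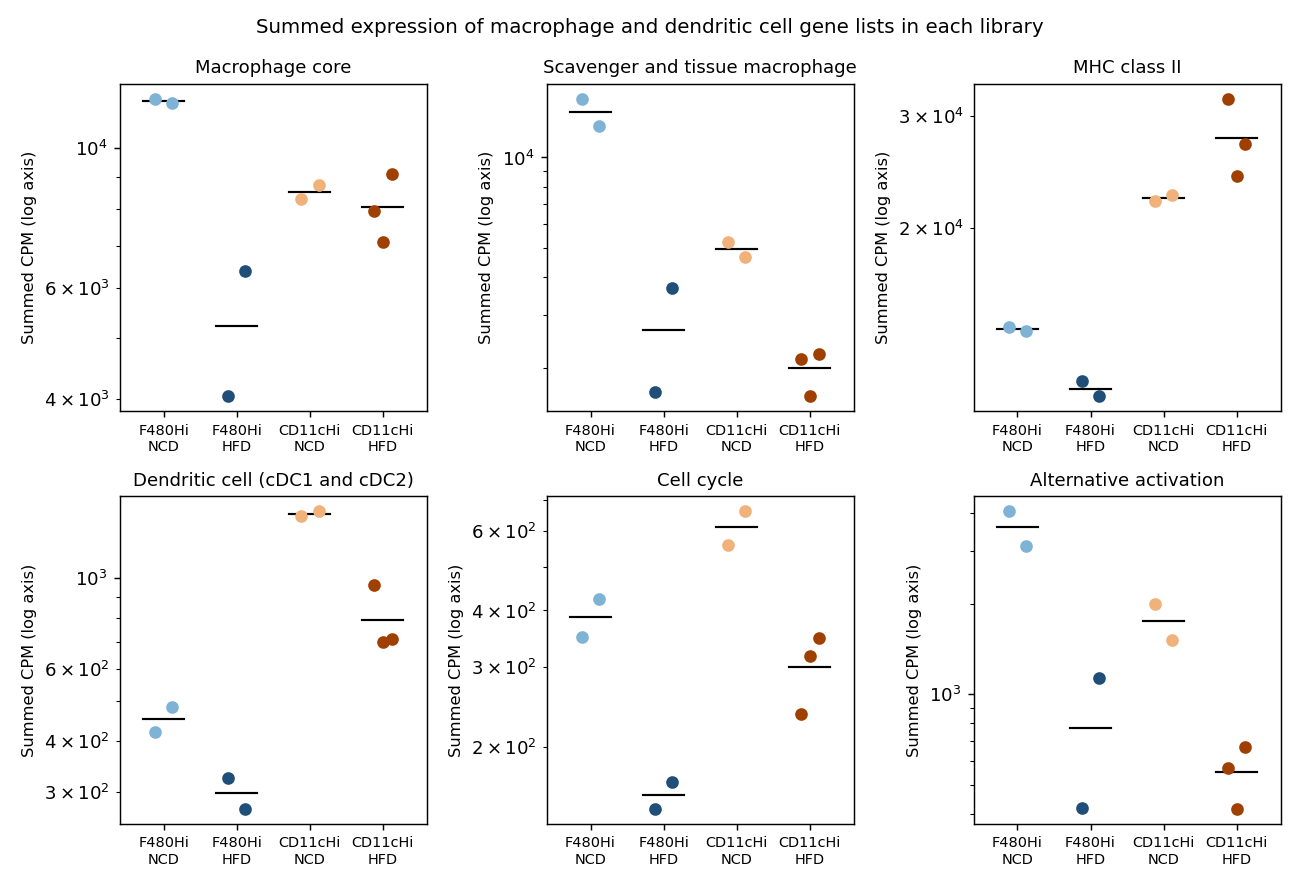
Summed CPM (log axis) of 6 gene lists in each library (points), with group means (lines). MHC class II and conventional dendritic cell lists lay higher in CD11cHi, and cell cycle, scavenger and alternative activation lists lay lower on HFD in both populations. The lower macrophage core sum of F480Hi on HFD (5220 CPM against 11900 on NCD) is removed by scaling to that list, by its construction.

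The population differences on the 2 diets were only partly alike. Across genes, which are not independent replicates, the log2 fold changes on NCD and HFD had a Pearson r of 0.378 and a Spearman rho of 0.153, and 52.7% had the same sign. Of the genes called, 127 were higher in CD11cHi on both diets (35.6 from independent lists) and 182 lower on both (22.8). Another 18 were higher on NCD and lower on HFD (45.8) and 20 the reverse (17.7). No library is shared between these 2 contrasts.

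The third comparison asks how the CD11cHi libraries differed between the diets. Part of the scavenger, alternative activation, chemokine, dendritic cell and cell cycle genes fell on HFD, and part of the endocrine transcripts rose. As lists these were called at the preset correlation, and with an estimated correlation they were not (adjusted p = 0.163, 0.274, 0.274, 0.163 for both dendritic lists, 0.315, and 0.319 for both endocrine lists). Of 29 scavenger and tissue macrophage genes 22 fell, 0 rose and 7 were not called (26 adjusted over the list alone; camera adjusted p = 3.32e-36, and adjusted p = 0.163 with an estimated correlation). Together they went from 4950 ± 396 CPM (SD, n = 2) to 1990 ± 332 (SD, n = 3). Folr2, a folate receptor gene of tissue macrophages (NM_008035, chromosome 7, 101839988 to 101845331), fell from 139 ± 34.4 to 6.53 ± 1.93 CPM (-4.45 ± 0.46, adjusted p = 0.000431). Igf1, a growth factor gene, fell by 2.91 ± 0.36 on the log2 scale (adjusted p = 0.00111). Gas6, a ligand for uptake of dying cells, fell by 3.34 ± 0.36 (adjusted p = 0.00057). Of 21 alternative activation genes 9 fell, 0 rose and 12 were not called (10 adjusted over the list alone; camera adjusted p = 1.59e-09, and adjusted p = 0.274 with an estimated correlation). Retnla (NM_020509, chromosome 16, 48842552 to 48844461), a gene induced by interleukin 4, fell from 376 ± 217 to 5.28 ± 6.99 CPM (-6 ± 0.79, adjusted p = 0.00132). The eosinophil chemokine gene Ccl24 fell by 5.24 ± 0.43 on the log2 scale (adjusted p = 0.000108).

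Chemokine genes fell in 7 of 21, with 0 higher and 14 not called (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.2e-08, and adjusted p = 0.274 with an estimated correlation). One was the neutrophil chemokine gene Cxcl2 (-3.05 ± 0.32, adjusted p = 0.000568). Dendritic cell markers fell in 4 of 10 for cDC1 (5 adjusted over the list alone; camera adjusted p = 3.05e-06, and adjusted p = 0.163 with an estimated correlation). They fell in 7 of 12 for the second list (9 adjusted over the list alone; camera adjusted p = 1.59e-09, and adjusted p = 0.163 with an estimated correlation). Examples were Naaa (-2.57 ± 0.35, adjusted p = 0.00157), Irf4 (-2.35 ± 0.37, adjusted p = 0.00344) and Fscn1 (-2.13 ± 0.27, adjusted p = 0.00119). NK cell markers fell in the same libraries in 5 of 10 with 5 not called (7 adjusted over the list alone; camera adjusted p = 8.39e-07, and adjusted p = 0.24 with an estimated correlation), from 79 ± 29.7 to 35 ± 2.21 CPM. Monocyte markers fell in 2 of 12 with 10 not called (3 adjusted over the list alone; camera adjusted p = 0.000817, and adjusted p = 0.319 with an estimated correlation), from 470 CPM in both libraries to 185 ± 27.5. Cell cycle genes fell in 5 of 33, with 28 not called (9 adjusted over the list alone; camera adjusted p = 6.16e-09, and adjusted p = 0.315 with an estimated correlation). An example was Mcm6 (-1.34 ± 0.21, adjusted p = 0.00358). The lipid uptake receptor gene Cd36 (-2.02 ± 0.28, adjusted p = 0.00157), Capg (-2.23 ± 0.35, adjusted p = 0.00344) and Anxa2 (-2.15 ± 0.31, adjusted p = 0.00213) fell. Their list, of lipid-associated macrophages, had 7 of 25 lower, 0 higher and 18 not called (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00532, and adjusted p = 0.584 with an estimated correlation), and its median turned positive with macrophage core scaling (0 higher, 4 lower). The sum of the lipid-associated macrophage list was higher on HFD (14500 ± 2270 CPM against 10600 ± 1110) while its median log2 fold change was -0.14, so the 2 differ in sign. The lysozyme gene Lyz1 (-4.05 ± 0.52, adjusted p = 0.00119) and the endothelin receptor gene Ednrb (-4.64 ± 0.59, adjusted p = 0.00112) were lower too.

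Genes that respond to tissue dissociation were lower on HFD in CD11cHi, in 11 of 24 with 0 higher and 13 not called (18 adjusted over the list alone; camera adjusted p = 2.23e-14, and adjusted p = 0.274 with an estimated correlation). Their sum was 3490 ± 648 CPM against 5860 ± 1130. Klf2 (-2.78 ± 0.30, adjusted p = 0.00057), Nr4a1 (-2.45 ± 0.36, adjusted p = 0.0024) and Klf4 (-2.15 ± 0.32, adjusted p = 0.00298) were among them. MHC class II genes were not called as a list (camera adjusted p = 0.416). Their sum was higher on HFD (27800 against 22400 CPM) while their median log2 fold change was -0.27, so the sum and the median differ in sign. The sort marker genes were not called by diet in CD11cHi, with Itgax at 0.63 ± 0.39 (adjusted p = 0.409), Adgre1 at 0.03 ± 0.23 (adjusted p = 0.962) and Itgam at -1.59 ± 0.46 (adjusted p = 0.064).

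Part of the endocrine markers were higher and part of the acinar markers lower in the same libraries. Beta cell markers rose in 4 of 15, with 11 not called (8 adjusted over the list alone; camera adjusted p = 1.36e-06, and adjusted p = 0.319 with an estimated correlation). An example was Scg2 (1.97 ± 0.30, adjusted p = 0.00303). Other endocrine markers rose in 7 of 10 with 3 not called (8 adjusted over the list alone; camera adjusted p = 5.06e-07, and adjusted p = 0.319 with an estimated correlation). The opioid precursor gene Pdyn (6.81 ± 0.50, adjusted p = 5.84e-05) and Tmem59l (4.66 ± 0.52, adjusted p = 0.000615) rose with them. So did the potassium channel gene Kcnk3 (4.15 ± 0.57, adjusted p = 0.00168) and the vitamin D binding protein gene Gc (3.74 ± 0.38, adjusted p = 0.000431). Acinar markers fell in 13 of 19, with 6 not called (19 adjusted over the list alone; camera adjusted p = 2.6e-23, and adjusted p = 0.274 with an estimated correlation). Their sum went from 29500 ± 10700 to 2330 ± 2500 CPM. Pla2g1b fell by 5.98 ± 0.59 on the log2 scale (adjusted p = 0.000362) and Zg16 by 4.67 ± 0.77 (adjusted p = 0.00454). Serpini2 had 428 counts on NCD and 3 on HFD, a ratio of 181 (61.6 to 882).

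By diet, 878 genes were called in CD11cHi, 401 higher and 477 lower on HFD, and 2887 had an unadjusted p under 0.05. The split was 232 and 1133 on log2(TPM + 1) and 168 and 921 on log2(TPM + 0.1), but more genes were higher than lower with DESeq2 (791 and 652), the stricter filter (452 and 415), islet and acinar genes left out of library sizes (444 and 440), macrophage core scaling (355 and 307) and without CD11cHi NCD replicate 1 (235 and 192). The count was 1367 with no expression filter, 1438 with only the groups compared, 520 with the replicate number as block, 105 with a beta cell score as covariate, 228 without CD11cHi NCD replicate 2, 427 without replicate 1, 382 without CD11cHi HFD replicate 3 and 534 without replicate 2.

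**Figure D3:**
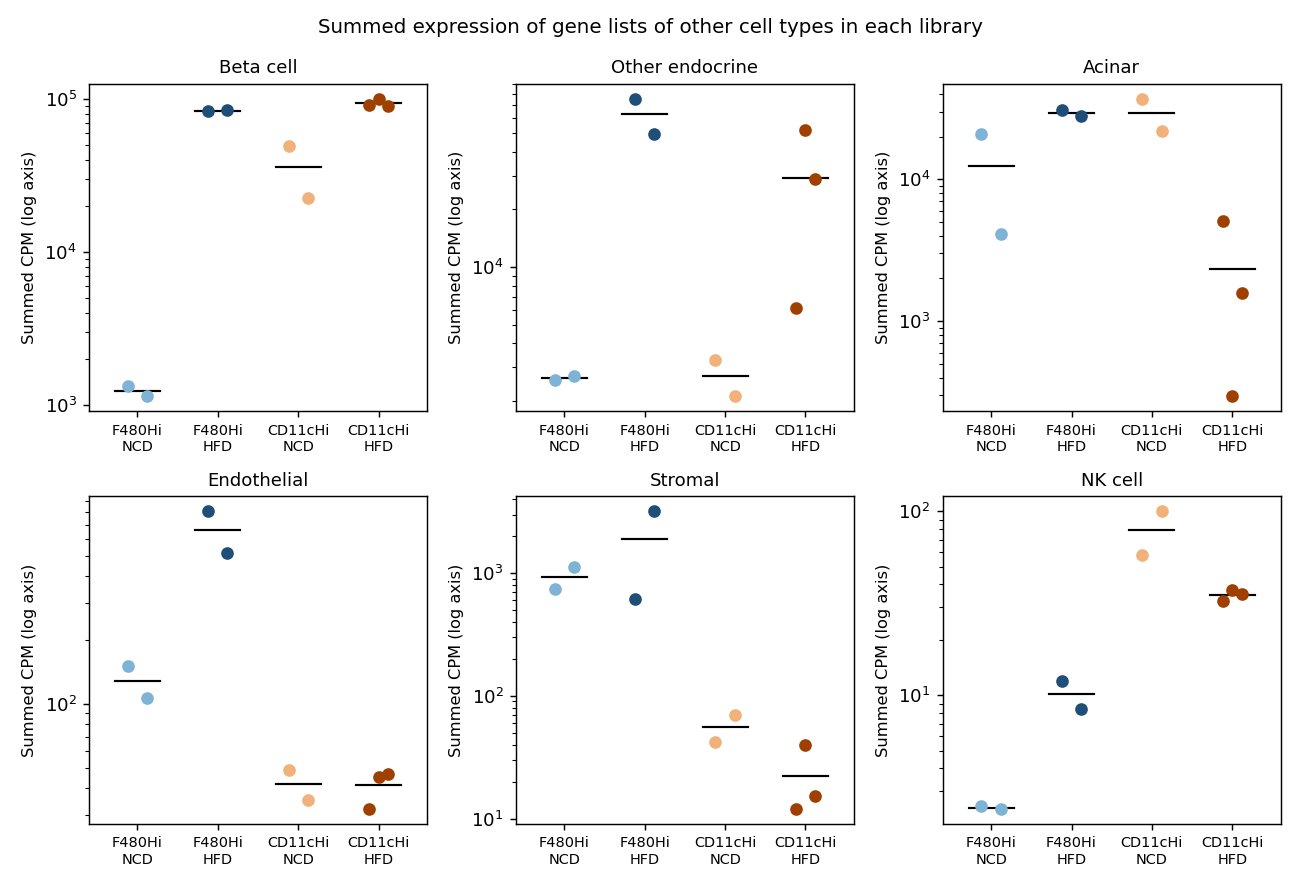
Summed CPM (log axis) of 6 marker lists of other cell types in each library (points), with group means (lines). Beta cell markers averaged 1230 CPM in F480Hi on NCD and 84200 on HFD, acinar markers were lowest in CD11cHi on HFD at 2330, and endothelial markers were highest in F480Hi on HFD at 660.

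The fourth comparison asks the same of the F480Hi libraries. Part of the macrophage core, scavenger, complement and cell cycle genes fell on HFD, and part of the beta cell, other endocrine, endothelial and ductal markers rose. None of these 8 lists kept its call with an estimated correlation (adjusted p = 0.347, 0.32, 0.579, 0.452, 0.262, 0.356, 0.345 and 0.262). Of 18 macrophage core genes 12 fell, 0 rose and 6 were not called (13 adjusted over the list alone; camera adjusted p = 1.92e-06, and adjusted p = 0.347 with an estimated correlation). Their sum went from 11900 ± 141 to 5220 ± 1660 CPM (SD, n = 2 each). This change is absent by construction when the libraries are scaled to that list (2 higher, 3 lower). Csf1r, the receptor of macrophage colony stimulating factor (NM_001037859, chromosome 18, 61105572 to 61131139), fell from 2130 ± 295 to 455 ± 85.9 CPM (-2.22 ± 0.33, adjusted p = 0.000441). Cx3cr1 fell by 2.39 ± 0.34 on the log2 scale (adjusted p = 0.000302). Adgre1 fell by 1.88 ± 0.26 (adjusted p = 0.000251) and Itgax rose by 2.91 ± 0.46 (adjusted p = 0.000671), while Itgam was not called (-1.21 ± 0.51, adjusted p = 0.105). The Adgre1 call was lost with macrophage core scaling.

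Scavenger and tissue macrophage genes fell in 23 of 29 in F480Hi, with 0 higher and 6 not called (26 adjusted over the list alone; camera adjusted p = 2.06e-18, and adjusted p = 0.32 with an estimated correlation). Summed, they went from 14200 ± 2120 to 2670 ± 1430 CPM. They included Folr2 (-3.74 ± 0.50, adjusted p = 0.000207), the phosphatidylserine receptor gene Timd4 (-4.59 ± 0.72, adjusted p = 0.000621) and Ccl24 (-4.52 ± 0.41, adjusted p = 1.57e-05). Also lower were Igf1 (-3.66 ± 0.42, adjusted p = 6.81e-05), Gas6 (-2.73 ± 0.39, adjusted p = 0.00032) and Stab1 (-2.53 ± 0.41, adjusted p = 0.000715). The alternative activation list had 10 of 21 lower, 3 higher and 8 not called (12 and 3 adjusted over the list alone; camera adjusted p = 0.000676, and adjusted p = 0.521 with an estimated correlation). Complement genes fell in 8 of 16, with 0 higher and 8 not called (10 adjusted over the list alone; camera adjusted p = 0.000242, and adjusted p = 0.579 with an estimated correlation). An example was C1qc (-1.55 ± 0.30, adjusted p = 0.00245). The sialic acid enzyme gene Cmah (-5.65 ± 0.37, adjusted p = 2.98e-06) and the erythropoietin receptor gene Epor (-5.93 ± 0.71, adjusted p = 9.2e-05) were among the largest falls. Erythroid markers fell in the same libraries, in 2 of 6 with 4 not called (6 adjusted over the list alone; camera adjusted p = 0.0334, and adjusted p = 0.616 with an estimated correlation). Together they went from 75 ± 20.8 to 5.19 ± 6.13 CPM.

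Lysosome genes fell in 14 of 32 with TMM, with 0 higher and 18 not called (14 adjusted over the list alone; camera adjusted p = 9.67e-05, and adjusted p = 0.48 with an estimated correlation). The list turned with macrophage core scaling to 12 higher and 0 lower. The lysosomal genes Ctsa, Grn and Npc1 had log2 fold changes of -1.61 ± 0.25 (adjusted p = 0.000644), -1.58 ± 0.33 (adjusted p = 0.0037) and -1.26 ± 0.21 (adjusted p = 0.000825). The Toll-like receptor and NF-kB list, with 9 of 26 lower and 17 not called (14 adjusted over the list alone; camera adjusted p = 0.000265, and adjusted p = 0.345 with an estimated correlation), turned in the same way to 9 higher and 2 lower. Its member Tlr4 fell by 1.88 ± 0.28 (adjusted p = 0.000467). Costimulation genes fell in 4 of 8, with 4 not called (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.345 with an estimated correlation). Among them, Cd86 (-1.19 ± 0.20, adjusted p = 0.00108) stood at 0.02 with macrophage core scaling and Cd83 (-1.38 ± 0.23, adjusted p = 0.000834) at 0.02 with a beta cell score as covariate. Cd36 fell by 2.53 ± 0.32 (adjusted p = 0.000148). Cell cycle genes fell in 17 of 33, with 0 higher and 16 not called (21 adjusted over the list alone; camera adjusted p = 2.07e-07, and adjusted p = 0.452 with an estimated correlation). Their sum went from 386 ± 53 to 156 ± 14.8 CPM. Kif11 (-3.09 ± 0.51, adjusted p = 0.000822) and Ccnb2 (-2.48 ± 0.54, adjusted p = 0.00508) were among them.

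Dissociation-responsive genes were lower in F480Hi on HFD as well, in 14 of 24 with 0 higher and 10 not called (18 adjusted over the list alone; camera adjusted p = 2.07e-07, and adjusted p = 0.452 with an estimated correlation). Examples were Klf2 (-3.03 ± 0.34, adjusted p = 6.8e-05) and Atf3 (-2.42 ± 0.33, adjusted p = 0.000221). Endoplasmic reticulum stress genes rose in 8 of 18 with TMM, with 0 lower and 10 not called (12 adjusted over the list alone; camera adjusted p = 0.0111, and adjusted p = 0.48 with an estimated correlation). On both TPM scales the list turned, and 2 were higher and 4 lower. Among the 8 genes that rose with TMM were the asparagine synthetase gene Asns (2.57 ± 0.54, adjusted p = 0.00392) and Creld2 (1.73 ± 0.36, adjusted p = 0.00368), and Asns followed beta cell markers (r = 0.925).

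Part of the markers of other pancreatic cells were far higher in F480Hi on HFD. Beta cell markers rose in 14 of 15, with 1 not called (15 adjusted over the list alone; camera adjusted p = 3.38e-32, and adjusted p = 0.262 with an estimated correlation). Their sum went from 1230 ± 127 to 84200 ± 849 CPM. The islet amyloid gene Iapp rose by 6.38 ± 0.46 (adjusted p = 5.31e-06) and the insulin gene Ins2, in part identical to Ins1, by 6.21 ± 0.53 (adjusted p = 9.23e-06). Other endocrine markers rose in 9 of 10 (9 adjusted over the list alone; camera adjusted p = 3.91e-07, and adjusted p = 0.356 with an estimated correlation). The peptide YY gene Pyy rose by 5.47 ± 0.89 (adjusted p = 0.000781). Endothelial markers rose in 10 of 11 with 1 not called (11 adjusted over the list alone; camera adjusted p = 1.92e-06, and adjusted p = 0.345 with an estimated correlation). Their sum went from 128 ± 31.8 to 660 ± 210 CPM. Examples were Plvap (3.64 ± 0.48, adjusted p = 0.000205) and Flt1 (3.64 ± 0.57, adjusted p = 0.000604). Ductal markers rose in 6 of 10 with 4 not called (6 adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.262 with an estimated correlation). Examples were Krt7 (5.17 ± 0.45, adjusted p = 1.02e-05) and Epcam (3.57 ± 0.32, adjusted p = 1.42e-05). Outside the lists, Pdyn (8.98 ± 0.58, adjusted p = 2.98e-06) and Muc4 (7.13 ± 0.43, adjusted p = 2.98e-06) rose. Serpina7 had 655 counts against 0 (at least 241-fold higher), and Defb1 had 722 against 1, a ratio of 797 (143 to 31500).

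In F480Hi 3708 genes were called by diet, 2099 higher and 1609 lower on HFD, and 5321 had an unadjusted p under 0.05. The split was 1340 and 6279 on log2(TPM + 1), 1260 and 6043 on log2(TPM + 0.1) and 8020 and 202 with macrophage core scaling. The count was 2268 without F480Hi NCD replicate 1 and 2322 without replicate 2. Endocrine transcripts separated the 2 diet groups of F480Hi completely. With a beta cell score as covariate edgeR called 0 genes (588 at unadjusted p under 0.05), with Plvap at -1.30, Asns at -3.56, Creld2 at -0.55, Kif11 at 0.86 and Ccnb2 at 0.77.

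Averaged over populations, 3845 genes were called by diet, 2073 higher and 1772 lower on HFD (5436 at unadjusted p under 0.05). Scavenger and tissue macrophage genes were lower in 26 of 29, with 0 higher and 3 not called (27 adjusted over the list alone; camera adjusted p = 9.13e-29, and adjusted p = 0.3 with an estimated correlation). Folr2 (-4.10 ± 0.34, adjusted p = 5.97e-06) and Ccl24 (-4.88 ± 0.30, adjusted p = 1.51e-06) fell, as did Retnla (-4.15 ± 0.57, adjusted p = 0.000197) and Cd36 (-2.27 ± 0.21, adjusted p = 1.19e-05). The diet differences of the 2 populations had a Pearson r of 0.459 and a Spearman rho of 0.455 across 14226 genes, and 65.3% had the same sign. Of the genes called, 363 were higher on HFD in both populations (59.2 from independent lists) and 225 lower in both (54). Another 4 rose in CD11cHi and fell in F480Hi (45.4) and 23 did the reverse (70.4). The split was 1329 and 6975 on log2(TPM + 1), 1297 and 6750 on log2(TPM + 0.1), 6305 and 394 with macrophage core scaling and 2131 and 2151 with a stromal score as covariate. With a beta cell score as covariate edgeR called 0 genes (600 at unadjusted p under 0.05).

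The last comparison tests whether the diet difference itself differed between the populations, as CD11cHi minus F480Hi. It called 889 genes, 277 positive and 612 negative (2965 at unadjusted p under 0.05). Of 18 macrophage core genes 12 fell on HFD in F480Hi (adjusted p = 0.347 with an estimated correlation), while in CD11cHi 1 rose, 1 fell and 16 were not called (1 and 1 adjusted over the list alone; camera adjusted p = 0.999). In the interaction they were positive in 8 of 18 with 0 negative and 10 not called (10 adjusted over the list alone; camera adjusted p = 1.36e-08, and adjusted p = 0.33 with an estimated correlation). With macrophage core scaling 0 were positive and 1 negative, with a list median of 0.16. Mertk, a receptor for dying cells (1.72 ± 0.29, adjusted p = 0.00628), the RNA sensor gene Tlr7 (1.91 ± 0.28, adjusted p = 0.00274) and the prostaglandin dehydrogenase gene Hpgd (2.70 ± 0.31, adjusted p = 0.000942) were positive. Others were Clec5a (2.60 ± 0.41, adjusted p = 0.00376) and Adam19 (2.58 ± 0.30, adjusted p = 0.000985). So was Adgre1 (1.92 ± 0.34, adjusted p = 0.00794), a call lost without CD11cHi NCD replicate 1 (1.75, adjusted p = 0.0605), with a beta cell score as covariate and with macrophage core scaling. Itgax was negative (-2.28 ± 0.58, adjusted p = 0.0384) and lost its call without any 1 of 7 libraries. These were replicates 1, 2 and 3 of CD11cHi HFD (adjusted p = 0.0549, 0.0585 and 0.0794), 1 and 2 of CD11cHi NCD (0.0966 and 0.11), 1 of F480Hi HFD (0.0964) and 1 of F480Hi NCD (0.151). Itgam was not called (-0.38 ± 0.69, adjusted p = 0.822).

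Beta cell and acinar markers were on the negative side of the interaction, and erythroid markers on the positive side. The 6 erythroid markers were not called singly (6 positive adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.549 with an estimated correlation). They are not separate measurements: Hba-a1 and Hba-a2 had the same counts on NCD (299 each in F480Hi and 3 in CD11cHi). In CD11cHi the list was near the floor, at 1.27 ± 1.51 CPM on NCD and 4.18 ± 7.03 on HFD. Beta cell markers were negative in 14 of 15 with 1 not called (15 adjusted over the list alone; camera adjusted p = 3.85e-40, and adjusted p = 0.151 with an estimated correlation). They included Iapp (-5.02 ± 0.51, adjusted p = 0.000586) and Nkx6-1 (-4.84 ± 0.70, adjusted p = 0.00284). Acinar markers were negative in 12 of 19 with 7 not called (19 adjusted over the list alone; camera adjusted p = 1.96e-21, and adjusted p = 0.33 with an estimated correlation). Among these were Pla2g1b (-5.92 ± 0.79, adjusted p = 0.002) and Zg16 (-5.92 ± 1.11, adjusted p = 0.0101; 0.18 with a beta cell score as covariate). Flt3 (-4.77 ± 0.61, adjusted p = 0.00153), the epithelial keratin gene Krt7 (-3.79 ± 0.54, adjusted p = 0.00271), Ncam1 (-3.04 ± 0.51, adjusted p = 0.00535; r = 0.953 with beta cell markers) and Hr (-6.53 ± 0.93, adjusted p = 0.00271) were negative too. The split was 640 and 361 on log2(TPM + 1), 533 and 298 on log2(TPM + 0.1) and 7 and 3505 with macrophage core scaling. The count was 1426 with DESeq2, 539 with the replicate number as block, 252 without CD11cHi NCD replicate 1, 542 without replicate 2, 462 without CD11cHi HFD replicate 3, 435 without F480Hi NCD replicate 1 and 362 without replicate 2. With a beta cell score as covariate edgeR called 0 genes (653 at unadjusted p under 0.05).

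**Figure D4:**
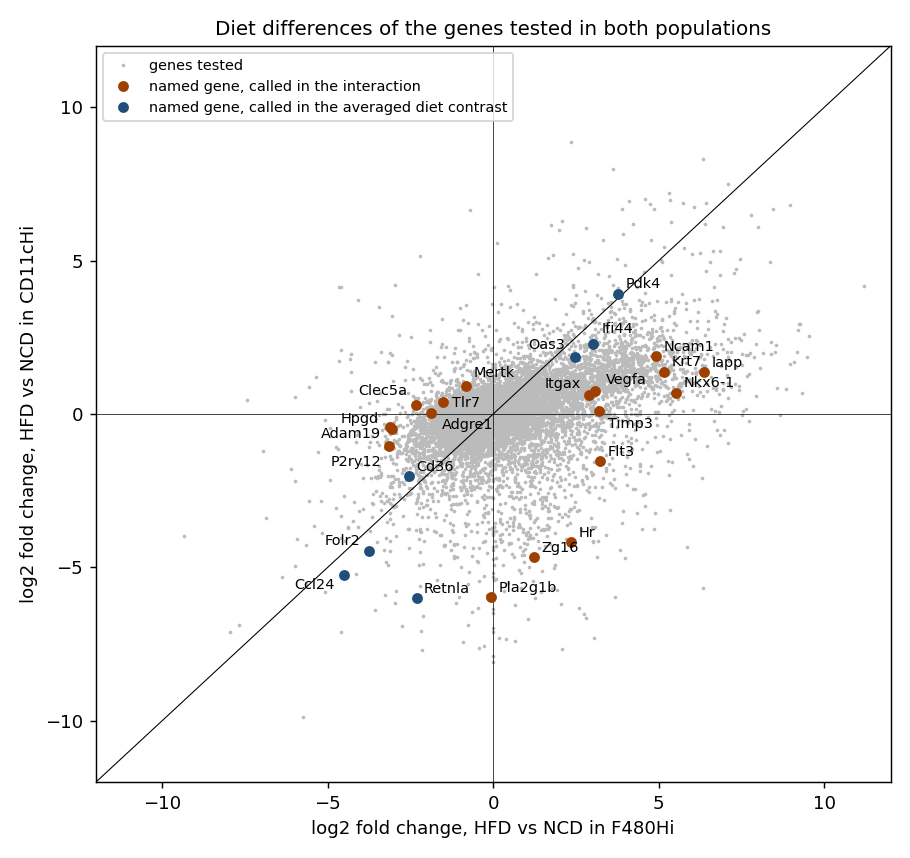
Log2 fold change on HFD against NCD in F480Hi (horizontal axis) and CD11cHi (vertical axis) for 14226 genes (grey), with named genes called in the interaction (brown), named genes called in the averaged diet difference (blue) and a line of equal change. Folr2 and Ccl24 lie near that line and Iapp far below it, and values of genes with near-zero counts depend on the prior count.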

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

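The tests in this section were chosen only after the results they concern had been seen.

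Macrophage core genes were lower in F480Hi on HFD in 12 of 18 (adjusted p = 0.347 with an estimated correlation). Dilution of macrophage RNA by RNA without MHC class II transcripts would leave the ratio of core to MHC class II counts unchanged. Its log2 value changed by -0.92 (pooled SD 0.27), with -1.51 and -0.78 on HFD against -0.22 and -0.22 on NCD. Without F480Hi HFD replicate 1 the change was -0.55 and without replicate 2 -1.29, so its size rests on replicate 1. Leaving out any 1 other library gave -0.92 again and adds little. The values argue against such dilution as the whole cause, but with 2 libraries in each group they do not exclude it. Dilution by RNA that holds MHC class II transcripts is not tested by this ratio. CD11cHi-type cells among the F480Hi cells on HFD could also lower the core genes relative to MHC class II. On that scale 14 of 18 core genes (77.8%) lay between F480Hi on NCD and CD11cHi on HFD, against 38.8% of 8723 genes at 10 CPM or more. Every gene was divided by the same MHC class II sum, so this count largely restates the change in ratio above. The core genes are not separate checks, and the count cannot decide for or against such cells. In CPM, however, the core sums of F480Hi on HFD (4040 and 6390) lay below those of F480Hi on NCD (at least 11800) and CD11cHi on HFD (at least 7110). Its MHC class II sums (10900 and 11500) also lay below both (at least 13800 and 24200). These values argue against a mixture of these cells alone, while a mixture further diluted by RNA of other cells stays open. Mixed cells and a change within cells cannot be told apart here, because a changed macrophage could take the same relative values. An effect of diet stays open and untested.

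MHC class II genes were higher in CD11cHi, in 5 of 11 on NCD and 11 of 11 on HFD (adjusted p = 0.194 and 0.0985 with an estimated correlation). The list median stayed positive under the 6 other scalings on both diets, with a lowest value of 0.41 on log2(TPM + 1). None of these scalings thus turned the direction. Some of them moved genes little on NCD, so scaling at large is not excluded as a cause. Dendritic cells in the sort as the source, and a difference between the macrophages themselves, stay open and untested.

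Endocrine genes rose on HFD in part: 4 of 15 beta cell and 7 of 10 other endocrine markers in CD11cHi (adjusted p = 0.319 each with an estimated correlation), and 14 of 15 and 9 of 10 in F480Hi (adjusted p = 0.262 and 0.356). Carry-over of whole pancreas of unchanged make-up would leave the log2 ratio of endocrine to acinar counts unchanged. In CD11cHi this ratio changed by 6.16 (pooled SD 1.69, and 4.91 to 7.29 with 1 library left out). These values argue against such carry-over as the whole cause in CD11cHi, but with so few libraries they do not exclude it. In F480Hi the ratio changed by 3.57 (SD 1.69), past 2 pooled SD, but 6 of the 9 runs with 1 library left out were not (2.40 to 3.62). In all of these but the run at 2.40 the change stayed at 3.52 to 3.62 while the pooled SD rose to 1.88. The argument against such carry-over in F480Hi is thus weak. Carry-over from islets of unchanged make-up could be the source: the log2 ratio of other endocrine to beta cell counts changed by 1.49 (SD 1.01) in CD11cHi and -1.56 (SD 1.01) in F480Hi, where it was 0.97 and 1.25 on NCD and -0.14 and -0.77 on HFD. The pooled SD keeps this open and comes mainly from CD11cHi HFD replicate 1, without which it is 0.39 and the changes are 2.36 and -1.56; whether islet RNA was free or taken up by macrophages was not tested.

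Relabelling the libraries tested whether the counts could come from any split. For the averaged population difference the real split called 1797 genes and the highest of the others 889, rank 1 of 60, and the median of the others was 0. For the averaged diet difference the real split called 3845 and the highest other 2848, also rank 1 of 60, with a median of 0. Rank 1 of 60 makes a chance split of independent libraries unlikely for both and does not exclude it. The labels do not say that the libraries are independent. The other splits mix the real groups, which widens the spread within groups, so their median of 0 is not what chance alone would give. A split that swaps the labels of 1 whole stratum is the interaction itself, with 889 genes.

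The interaction called 889 genes. Its sort marker values were -2.28 for Itgax and 1.92 for Adgre1. Positive values were 2.70 for Hpgd, 2.60 for Clec5a, 2.58 for Adam19, 1.72 for Mertk, 1.91 for Tlr7 and 2.09 for P2ry12. Negative values were -2.33 for Vegfa, -4.77 for Flt3, -5.02 for Iapp, -4.84 for Nkx6-1, -5.92 for Pla2g1b, -5.92 for Zg16, -3.11 for Timp3, -3.79 for Krt7, -3.04 for Ncam1 and -6.53 for Hr. Camera adjusted p was 1.36e-08 for macrophage core genes and 9.22e-09 for lysosome genes (0 positive and 2 negative with macrophage core scaling, where the list turns). It was 0.0229 for cell cycle genes and 0.0341 each for efferocytosis, Toll-like receptor and iron genes, and these 4 lists turn with that scaling too. Among other cells it was 3.85e-40 for beta, 0.0103 for other endocrine, 1.96e-21 for acinar, 1.05e-09 for ductal, 2.44e-08 for endothelial, 0.0229 for stromal, 0.0229 for T cell, 2.39e-05 for monocyte, 0.0019 for erythroid and 0.0109 for Schwann cell and neural markers. With an estimated correlation 0 of these 16 lists held (lowest adjusted p = 0.083, ductal). With the replicate number as block 11 held, and cell cycle (adjusted p = 0.111), efferocytosis (0.0741), Toll-like receptor (0.1), iron (0.126) and erythroid genes (0.445) did not.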

How the results depend on the processing

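Of 152 named called pairs of gene and comparison, chosen partly because their call held with any 1 library left out, all 152 gave the same result with RLE scaling, islet and acinar genes left out of library sizes, no filter, a stricter filter and rRNA-derived genes removed. DESeq2 kept 151, and voom, both TPM scales and the replicate block 150 each. Macrophage core scaling kept 130 (21 weaker, 1 reversed), a stromal score 103 (43 weaker, 6 reversed) and a beta cell score 44 (98 weaker, 10 reversed). Reversed with the beta cell score were Fbn1 (0.09), Tnxb (0.09) and G6pc2 (-0.93) on NCD, Cd83 (0.02), Kif11 (0.86), Ccnb2 (0.77), Asns (-3.56), Creld2 (-0.55) and Plvap (-1.30) for diet in F480Hi, and Zg16 (0.18) in the interaction. Reversed with the stromal score were Itgax (-0.05) and Cx3cr1 (-0.17) on HFD and Pf4 (2.35), Lyve1 (0.66), Cbr2 (1.29) and Xcr1 (-0.04) averaged, and with macrophage core scaling Cd86 (0.02) for diet in F480Hi. Both lists differed strongly between groups, with beta cell sums of 1230 CPM in F480Hi on NCD and 84200 on HFD. Stromal sums on HFD were 22.4 CPM in CD11cHi and 1900 in F480Hi. As covariates such scores take up group differences whatever their source. Calls lost or reversed with them therefore do not show where the RNA came from. The cause was not tested. Calls on NCD (1214) were 1935 with only the groups compared, 0 with the beta cell score, 105 with the stromal score and 389 to 1570 with 1 library left out. On HFD (1429) they were 945 with only the groups compared, 941 with the beta cell score, 3727 with macrophage core scaling, 17 with the stromal score and 624 to 1934 with 1 library left out. Averaged over diets (1797) they were 0 with the beta cell score, 5 with the stromal score and 1143 to 2471. For diet in CD11cHi (878) they were 1367 with no filter, 1443 with DESeq2, 1438 with only the groups compared, 105 with the beta cell score, 1365 on log2(TPM + 1) and 228 to 1266. For diet in F480Hi (3708) they were 0 with the beta cell score, 7619 and 7303 on the TPM scales, 8222 with macrophage core scaling and 2268 to 3844. Averaged over populations (3845) they were 0 with the beta cell score, 8304 and 8047 on the TPM scales, 6699 with macrophage core scaling and 2621 to 3959. The interaction (889) gave 1426 with DESeq2, 0 with the beta cell score, 3512 with macrophage core scaling and 252 to 956. The correlation of population differences (0.378) was 0.264 with no filter, 0.074 with the beta cell score, 0.254 and 0.313 on the TPM scales, 0.685 with the stromal score and 0.281 to 0.377 with 1 library left out. That of diet differences (0.459) was 0.312 with no filter, 0.535 with the stricter filter, 0.679 with the beta cell score, 0.511 on log2(TPM + 1) and 0.349 to 0.464. Of 133 called lists 6 held with an estimated correlation and 125 with the block. With fry 89 were called in the same direction, but fry tests a list against no change and camera tests it against the other genes. Replicate numbers do not pair samples in the labels; with the number as block the counts were 1046, 866, 1480, 520, 3321, 3282 and 539 in the order above. Residuals of same-numbered libraries correlated from -0.026 to 0.105 and of others from -0.105 to 0.081, and 7 of 8 libraries correlated best with their own number. In a group of 2 the residuals mirror each other. Between 2 such groups, values for different numbers are thus same-number values with the sign turned. The 8 libraries are not separate checks, and the result is at most a weak hint from the data.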

Other observations

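Purine receptor genes changed in opposite directions with diet in F480Hi. P2ry12, a receptor for ADP on tissue macrophages (NM_027571, chromosome 3, 59216271 to 59262831), fell from 77.7 ± 4.86 to 8.81 ± 0.874 CPM (log2 fold change -3.14 ± 0.23, adjusted p = 5.92e-06), and P2ry1 (NM_008772, chromosome 3, 61002785 to 61008982), another ADP receptor, rose from 1.2 ± 0.566 to 22.2 ± 2.20 CPM (4.19 ± 0.40, adjusted p = 2.07e-05). P2ry1 followed the beta cell markers over the groups, at 1.2, 6.75, 20.9 and 22.2 CPM in F480Hi on NCD, CD11cHi on NCD, CD11cHi on HFD and F480Hi on HFD, against beta cell sums of 1230, 36100, 94300 and 84200 CPM (r = 0.961 over the 9 libraries), so its rise cannot be assigned to macrophages. Of 14 purinergic genes 6 fell, 1 rose and 7 were not called (6 and 1 adjusted over the list alone; camera adjusted p = 0.108). The diet difference of P2ry12 was more negative in F480Hi than in CD11cHi (interaction 2.09 ± 0.30, adjusted p = 0.00279).

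Vegfa, a growth factor gene for blood vessels (NM_001025250, chromosome 17, 46016993 to 46032377), rose in F480Hi from 7.22 ± 1.03 to 61.4 ± 14.8 CPM (3.09 ± 0.26, adjusted p = 9.23e-06), with an interaction of -2.33 ± 0.33 (adjusted p = 0.00264), and on NCD it was higher in CD11cHi (2.36 ± 0.26, adjusted p = 0.00021). Vegfa too followed the beta cell markers (r = 0.991), at 7.22, 37.1, 62.6 and 61.4 CPM in the same order of groups, so neither its diet nor its population difference can be assigned to macrophages. Growth factor genes as a list had 5 higher, 7 lower and 13 not called (7 and 7 adjusted over the list alone; camera adjusted p = 0.778).

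Among interferon-response genes, Ifi44 (2.66 ± 0.39, adjusted p = 0.000328) and Oas3 (2.17 ± 0.36, adjusted p = 0.000721) rose on HFD averaged over populations, in a list of 36 with 8 higher, 2 lower and 26 not called (8 and 2 adjusted over the list alone; camera adjusted p = 0.118). In CD11cHi alone 6 rose, 1 fell and 29 were not called (8 and 2 adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.584 with an estimated correlation). There the direction turned on the TPM scales, with 1 higher and 2 lower on log2(TPM + 1) and 0 and 2 on log2(TPM + 0.1). Ifi44 also moved with other endocrine markers (r = 0.801) and Oas3 with beta cell markers (r = 0.849), so neither rise can be assigned to macrophages with certainty. Pdk4, which limits glucose oxidation, rose by 3.85 ± 0.50 (adjusted p = 0.000135). It followed the other endocrine markers (r = 0.966), at 0.807, 2.09, 12.1 and 28.7 CPM in CD11cHi on NCD, F480Hi on NCD, CD11cHi on HFD and F480Hi on HFD, against sums of 2700, 2640, 29000 and 62800 CPM, so its rise cannot be assigned to macrophages. Of 20 fatty acid oxidation genes 4 rose, 3 fell and 13 were not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.97). The matrix protease gene Mmp12 was higher in CD11cHi on NCD (4.60 ± 0.69, adjusted p = 0.0017). Timp3 was lower in CD11cHi on HFD (-6.23 ± 0.35, adjusted p = 1.26e-06) and followed endothelial markers (r = 0.955). Of 4 sex-linked genes 0 were called by diet averaged over populations (camera adjusted p = 0.821).

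The authors' deposited table calls 4011 genes by diet in F480Hi, 2407 higher and 1604 lower, and 3596 of them were called here in the same direction with 0 opposite. For diet in CD11cHi, which it names F4/80Low, the authors' deposited table calls 1456 genes (797 higher, 659 lower), with 864 shared and 0 opposite. Its population comparisons call 1623 (1034 higher, 589 lower) and 1832 genes (823 higher, 1009 lower) in the authors' deposited table, with 1184 and 1392 shared and 0 opposite. Log2 fold changes of the authors' deposited table correlate with those here at 0.962, 0.939, 0.933 and 0.952 in this order; both come from the same libraries. The second population comparison of the authors' deposited table is headed NCD, but its values correlate at 0.952 with the HFD comparison and at 0.341 with the NCD one, so it was read here as HFD, a reading taken from the values alone.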
